A study of Mus musculus with 7 samples.

How the data were processed

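Whole kidneys from mouse embryos at E15.5 were profiled by RNA-seq in 7 libraries, 3 controls and 4 mutants. Per the labels' protocols, RNA was extracted with a Qiagen RNeasy kit and libraries were made with a stranded kit, NEB Ultra II Directional. Groups and replicate numbers were taken from the sample titles. The series text describes pairs of kidneys from mutant embryos and control littermates but does not say how many embryos went into a library, so p-values measure the spread between these samples. Per the submitters' processing notes, the tools were FastQC 0.11.5, Trim Galore 0.5.0, STAR 2.6.0c, HTSeq 0.6.1p2 and DESeq2, and the genome build was mm39 (GRCm39); the strand setting of the counting is not given.

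The authors deposited a single table of 16167 genes with versioned Ensembl identifiers and symbols. Per the file headers, it holds an FPKM value per library and the columns of a DESeq2 comparison: the mean of normalized counts (baseMean), the log2 fold change with its standard error, the test statistic, the p-value and the adjusted p-value. The baseMean column is a normalized signal that the authors made from counts and size factors, and the deposited test statistic is a score equal to the fold change over its error. The deposited log2 fold change and p-value columns were copied and not recomputed, and 14 genes have no p-value. The lowest deposited mean of normalized counts was 18.5, so genes with fewer counts are not listed. How the authors defined gene length for the FPKM values is not recorded. The deposited FPKM were checked against the deposited fold changes: for genes with a mean count above 1000 the 99th percentile of the absolute difference between both log2 values was 0.0022.

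Counts per library were recovered from the table. Mean count, share of FPKM and a size factor per library gave values within 0.05 of a whole number for 100% of all entries, and depth is the sum of these counts. It ran from 40511920 reads (control replicate 3) to 69028943 (control replicate 1). At 1 FPKM a gene of median length had 142 to 241 reads. Averaged over the genes tested, differences between libraries exceeded counting error, which need not hold for each gene near that level. Because the deposited unit is FPKM, the main test used FPKM and not these counts.

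Genes with an FPKM of at least 1 in at least 3 libraries were kept (13466; 2701 left out). The 4 mutants were compared with the 3 controls in limma 3.58.1 (R 4.3.3) on log2(FPKM + 1), with trended and robust empirical Bayes, two-sided, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed, rose or fell by sign. Irx3 and Irx5 were also compared by an exact permutation test of the difference of means over the 35 splits. Gene lists with at least 3 tested members (25 lists of cell types, pathways and RNA quality markers) were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists; the members of each list were also adjusted over the list alone. The groups, tests, lists, most alternative settings and the rule for named genes were set before the data were examined. The rule named the genes of the targeted locus and its relatives, the 10 largest rises and the 10 largest falls among changed genes with groups apart (without model names), up to 4 changed members of each list or the 2 with the smallest p if none changed, and the Y-linked genes. It gave 79 genes, of which 39 changed; 3 of the 79 are part of the counts and list tests and are not reported one by one here.

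The alternative settings fixed then were a pseudocount of 0.1, no filter, a minimum of 5 FPKM, quantile normalization, median-of-ratios size factors, limma's array weights, the replicate number as a block, limma without trend and robust steps, the deposited adjusted p, leaving out each library, an estimated correlation and fry. Added after seeing the data were limma-voom on the recovered counts, removal of each library's trend on transcript length (lowess with a span of 0.3), the log2 ratio of embryonic to adult beta-globin as a covariate, and exact permutation of list means. A covariate for sex was not run, since Y-linked genes were expressed in every library. If libraries pool embryos, that does not show an equal male share, and a sex difference was not tested. The pipeline was tested on simulated counts for the same 13466 genes and 7 libraries with 200 genes changed: limma called 60%, 80%, 94% and 98% of genes changed by 1.5, 2, 4 and 8 fold, and 8 of its 174 calls were false. Genes were drawn independently of each other, so shifts shared by many genes of a library were not simulated.

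Tables and plots used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The reference annotation at hand, GENCODE M21, is on the GRCm38 assembly and not on the build of the table, so no coordinates are given; it served only to find which genes neighbour Six3 and Irx3, and 16150 of the 16167 identifiers were found in it.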

Results

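RNA from whole mouse kidneys at E15.5 was sequenced in 7 libraries. The 4 mutant libraries came from embryos with floxed alleles of Irx3 and Irx5 on both chromosomes and Six2-Cre, a Cre recombinase active in the nephron progenitors of the kidney. The 3 control libraries came from littermates with a floxed allele on 1 chromosome, and their labels name no Cre. Irx3 and Irx5 encode Iroquois homeobox transcription factors and lie next to each other. The design asks how the kidney's RNA differs when both genes are deleted in the nephron lineage. Since the control labels name no Cre, effects of the deletion and of the Cre transgene cannot be told apart. Reads in the 16167 listed genes, recovered from the deposited values, came to 69028943, 59518537 and 40511920 for control replicates 1 to 3 and to 53497462, 46255680, 45539155 and 51702442 for mutant replicates 1 to 4. No 2 libraries agreed within counting noise, since the lowest chi-square per gene between any pair was 23.6. Values below are FPKM as mean ± SD (n = 3 controls, n = 4 mutants), and fold changes are mutant minus control on the log2(FPKM + 1) scale, which understates the change of genes with low values.

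Irx3 RNA was lower in all 4 mutant libraries, and Irx5 RNA was not. Irx3 (ENSMUSG00000031734.14) stood at 14.7, 14.2 and 12.7 FPKM in the controls and at 6.63, 3.99, 5.57 and 6.75 FPKM in the mutants, a log2 fold change of -1.16 (SE 0.15; limma adjusted p = 0.0144). The exact permutation test over the 35 splits of the libraries gave p = 0.0286, two-sided, the smallest it can give. Irx5 (ENSMUSG00000031737.12) was at 1.36, 1.55 and 1.59 FPKM in the controls and at 2.05, 0.895, 1.13 and 2.03 in the mutants, with an exact permutation p of 0.943, and rested on 131 to 345 reads per library. The labels do not say which part of either gene is removed, and reads from parts that remain would still be counted, so the Irx5 value does not check the deletion. Irx1 and Irx2, the other Iroquois genes tested, had log2 fold changes of -0.66 (SE 0.20) and -0.68 (SE 0.16) that missed the threshold (limma adjusted p = 0.182 and 0.0831). Both were lower in the deposited DESeq2 test (adjusted p = 0.029 and 0.0044), and both also belong to the loop of Henle list below. Fto and Rpgrip1l, which neighbour the locus, were at 10.3 and 2.98 FPKM in controls and 10.3 and 3.30 FPKM in mutants.

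Six3 (ENSMUSG00000038805.11), a homeobox gene best known from the developing eye and forebrain, showed the largest rise of all changed genes. It was at 0.047 ± 0.027 FPKM in controls (6, 19 and 15 reads) and at 5.01 ± 0.45 FPKM in mutants (1522, 1114, 1356 and 1419 reads), a ratio of mean FPKM of 106.5 and a log2 fold change of 2.52 (SE 0.086; limma adjusted p = 5.21e-06). Six2, the adjacent gene and the source of the Cre driver's name, was at 53.5 ± 8.03 FPKM in controls and 41.1 ± 8.52 in mutants, a difference that missed the threshold (log2 fold change -0.39, SE 0.17; limma adjusted p = 0.384).

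**Figure D1:**
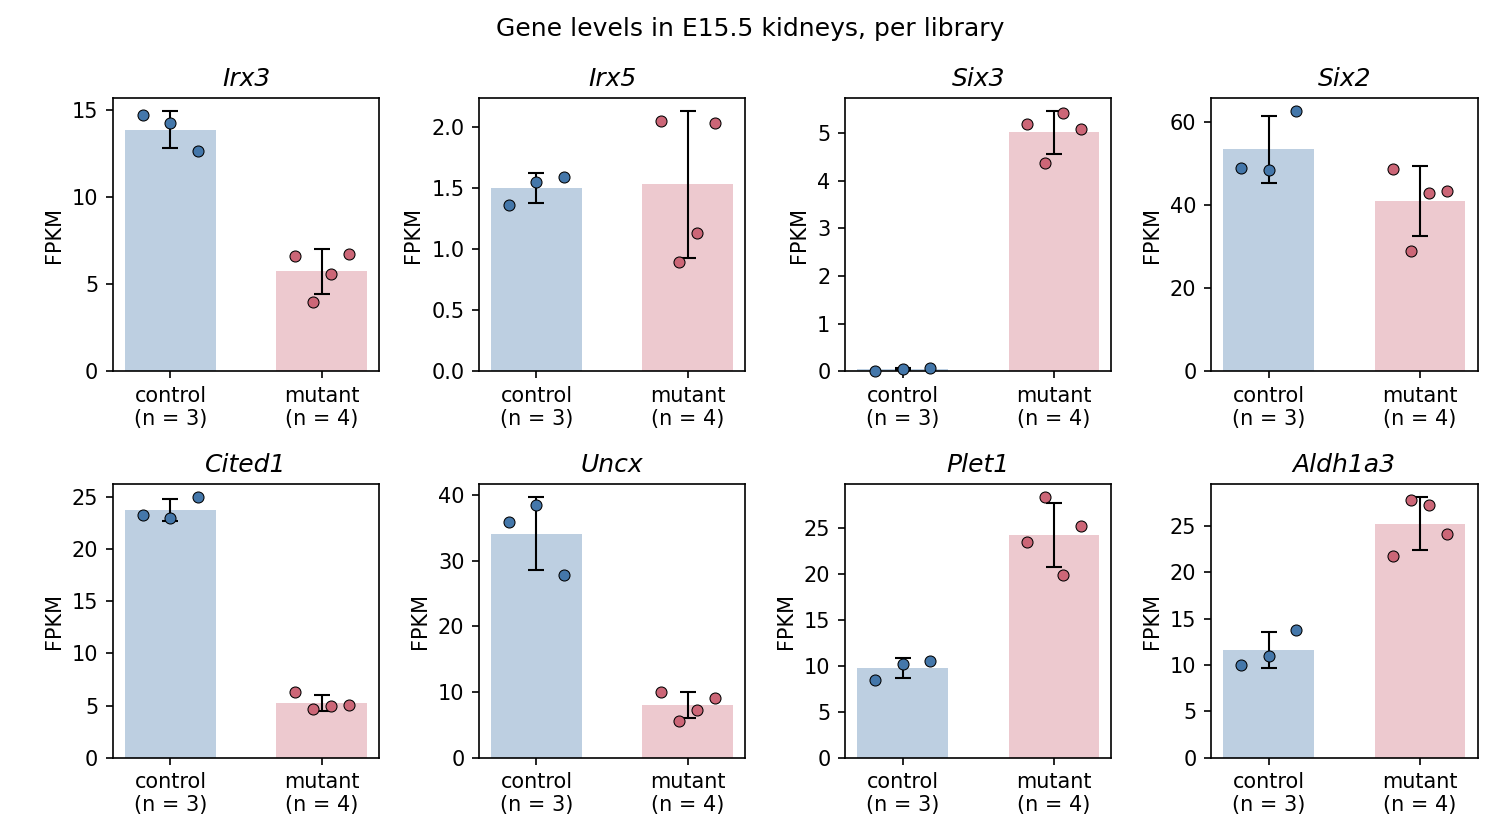
FPKM (vertical axes, each from 0) of 8 genes in control (n = 3) and mutant (n = 4) kidneys; points are libraries, bars are means and error bars are SD. The mutant libraries lie apart from the controls for Irx3, Six3, Cited1, Uncx, Plet1 and Aldh1a3, and overlap them for Irx5 and Six2.

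Across the 13466 genes tested, limma called 206 changed at an adjusted p under 0.05, with 64 higher and 142 lower in mutants. All mutant libraries lay on the same side of all controls for each of the 206, and for 1958 genes in all (14.5% of those tested, against 5.7% by chance). After Six3, the largest rises included those of Sprr2g (log2 fold change 2.02, SE 0.30), Spink8 (1.38, SE 0.21), Plet1 (1.23, SE 0.12), Aldh1a3 (1.07, SE 0.12) and Cldn23 (1.00, SE 0.12), followed by Ecm1, Fam3d and Tacr3 with 0.77 to 0.84. Aldh1a3 makes retinoic acid, and Cldn23 encodes a claudin of tight junctions. The largest falls included those of Cited1 (-1.99, SE 0.095) and Uncx (-1.98, SE 0.18), then the neurotrophic ligand gene Nrtn (-1.62, SE 0.29), and the transporter genes Slc3a1 (-1.50, SE 0.28) and Slc22a19 (-1.48, SE 0.24). Ugt2b37, Meox2, Rdh19 and Cyp2j5 fell by 1.33 to 1.41 on the log2 scale; 3 of these encode enzymes and Meox2 a homeobox factor. Sprr2g, Slc22a19, Ugt2b37 and Cyp2j5 belong to families of similar genes, and their values are uncertain where the counting could not tell the copies apart. The count depended on which libraries were used, and leaving 1 out also lowers the power of the test. It was 14, 11 and 54 without control replicates 1, 2 and 3, and 486, 42, 124 and 33 without mutant replicates 1, 2, 3 and 4. Of the 39 named genes that changed, 5, 4 and 18 kept their call without control replicates 1, 2 and 3, and 37, 11, 26 and 12 without mutant replicates 1 to 4; Six3, Cited1, Uncx and Plet1 kept it in all 7 omissions. With a minimum of 5 FPKM in 3 libraries, 31 genes were higher and 29 lower (51.7% higher, against 31.1% as first tested).

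Nephron progenitor genes fell as a list, but its members moved apart. Of 14 tested, 5 fell, 1 rose and 8 did not pass; adjusted over the list alone, 5 fell and 2 rose. Cited1 (ENSMUSG00000051159.17), a transcriptional coregulator of the least committed progenitors, went from 23.8 ± 1.07 to 5.25 ± 0.74 FPKM (limma adjusted p = 4.6e-05). Uncx (ENSMUSG00000029546.13), a homeobox gene, went from 34.1 ± 5.56 to 7.99 ± 1.94 FPKM (limma adjusted p = 0.0049). Meox1 and Tmem100 had log2 fold changes of -0.90 (SE 0.15) and -0.74 (SE 0.083). The remaining changed members, named after their values were seen, were Spock2, which fell (-0.49, SE 0.067), and Crym, which rose (0.43, SE 0.059). The list's median was -0.25 (camera adjusted p = 5.16e-05; adjusted p = 0.129 with an estimated correlation). Its calls came to 2, 2 and 3 lower without control replicates 1, 2 and 3, to 3 lower without mutant replicate 2 or 4, and the rise of Crym was lost without control replicate 1 or 2 or mutant replicate 2 or 4.

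Podocyte genes fell as a list. Of 15 tested members, 4 fell and 11 did not pass, and 9 fell when adjusted over the list alone; 11 of the 15 had a fold change below 0 and 4 above. Among those that fell, Nphs1 (nephrin) went from 7.46 ± 0.67 to 4.62 ± 0.71 FPKM, a log2 fold change of -0.60 (SE 0.11). Wt1, a transcription factor gene that is also expressed in nephron progenitors, had a log2 fold change of -0.41 (SE 0.056). The list's median was -0.41 (camera adjusted p = 5.9e-06; adjusted p = 0.173 with an estimated correlation). Without control replicates 1, 2 and 3 the calls came to 0, 0 and 1, and without mutant replicates 2, 3 and 4 to 0, 1 and 1.

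Genes of the differentiating tubule were lower in mutants as lists, with the lowest median in the proximal tubule. All 24 tested proximal tubule members had a fold change below 0, with a median of -0.76; 3 fell past the threshold, 21 did not pass, and 17 fell when adjusted over the list alone. Slc3a1, a subunit of an amino acid transporter, went from 6.12 ± 1.08 to 1.62 ± 0.84 FPKM. Slc22a6, an organic anion transporter, had a log2 fold change of -1.27 (SE 0.23), and the apolipoprotein gene Apom went from 3.29 ± 0.63 to 1.59 ± 0.33. The proximal list passed camera (adjusted p = 2.69e-15; adjusted p = 0.18 with an estimated correlation). In the loop of Henle list 3 of 16 members fell, 13 did not pass, and 12 fell when adjusted over the list alone. They were Bsnd, a chloride channel subunit (log2 fold change -1.11, SE 0.19), Cldn16, a claudin (-0.89, SE 0.15), and the transcription factor gene Pou3f3 (-0.49, SE 0.079). That list's median was -0.67 (camera adjusted p = 7.51e-12; adjusted p = 0.18 with an estimated correlation). In the distal and connecting tubule list 1 of 12 members fell, the potassium channel gene Kcnj10 (-0.54, SE 0.097), 11 did not pass, and 3 fell when adjusted over the list alone (median -0.34; camera adjusted p = 3.18e-05; adjusted p = 0.173 with an estimated correlation). Without mutant replicate 1 the proximal and loop calls came to 9 and 7; without any of the 3 controls, mutant replicate 2 or mutant replicate 4, they came to 0, as did the distal call, which was also lost without mutant replicate 3.

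The mean of the proximal list differed between libraries of a group as well. It was 3.63, 3.65 and 3.42 in control replicates 1 to 3 and 3.14, 2.81, 2.17 and 2.78 in mutant replicates 1 to 4, on the log2(FPKM + 1) scale. The embryonic beta-globin gene Hbb-y, which is replaced by adult globins as the embryo ages, stood at 1.34%, 1.39% and 3.45% of the FPKM of adult Hbb-bs in the controls and at 1.38%, 1.53%, 10.5% and 2.24% in the mutants. Hbb-bs is close in sequence to Hbb-bt, and reads of the pair could be split between them. The log2 ratio did not differ detectably between groups (exact permutation p = 0.657, n = 3 and 4). Within groups the proximal mean fell as the ratio rose, with a slope of -0.26 per log2 unit (exact permutation p = 0.0139 over 144 arrangements); without mutant replicate 3 the slope was -0.20 (exact permutation p = 0.0556 over 36 arrangements).

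**Figure D2:**
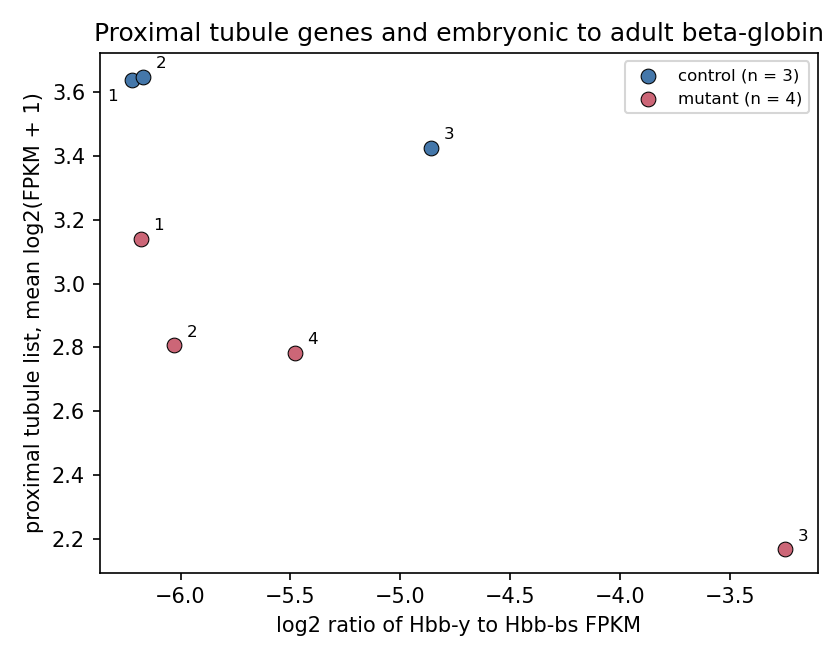
Mean log2(FPKM + 1) of the proximal tubule list (vertical axis) against the log2 ratio of Hbb-y to Hbb-bs FPKM (horizontal axis); each point is a library, numbered by replicate, with controls (n = 3) in blue and mutants (n = 4) in red. Every mutant lies below every control, and mutant replicate 3 has the highest ratio and the lowest proximal mean, 2.17.

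Genes of the early nephron, that is the renal vesicle and S-shaped body, were lower as a list, with a smaller median of -0.18 (camera adjusted p = 0.00896; adjusted p = 0.338 with an estimated correlation, the highest of its alternatives). Nor did it pass with array weights (adjusted p = 0.0598) or by fry (0.0557). None of its 16 tested members passed limma's threshold (0 changed, with 11 at an unadjusted p under 0.05; 1 lower by limma-voom and 3 lower in the deposited test), and adjusted over the list alone 8 fell and 3 rose. The ligand gene Fgf8 was at 6.86 ± 0.33 FPKM in controls and 3.16 ± 1.09 in mutants (limma adjusted p = 0.0609), and the Notch ligand gene Dll1 had a log2 fold change of -0.43 (SE 0.11; limma adjusted p = 0.0891). The Notch pathway list, which shares Dll1 and Jag1 with it, was also lower (median -0.24; camera adjusted p = 0.000161; adjusted p = 0.173 with an estimated correlation). Of its 13 tested members 0 changed by limma, with 7 at an unadjusted p under 0.05, 7 lower when adjusted over the list alone, 0 by limma-voom and 6 lower in the deposited test. The glycosyltransferase gene Lfng was at 24.2 ± 1.61 FPKM in controls and 16.5 ± 2.70 in mutants (limma adjusted p = 0.0695), and the target gene Hey1 at 28.8 ± 2.46 and 19.8 ± 3.59 (limma adjusted p = 0.0891). Without mutant replicate 1, 4 Notch members and 1 early nephron member passed, all lower.

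Stromal genes were higher as a list by camera, with overlap between the groups. Of 22 tested members 3 rose and 19 did not pass; adjusted over the list alone 10 rose and 1 fell. Aldh1a2, which makes retinoic acid, went from 140 ± 0.13 to 195 ± 7.91 FPKM (limma adjusted p = 0.0156), and Cldn11 and Ntn1 had log2 fold changes of 0.67 (SE 0.12) and 0.47 (SE 0.092). The median was 0.29 (camera adjusted p = 5.56e-07; adjusted p = 0.173 with an estimated correlation). The list means were 5.10, 4.97 and 4.72 in control replicates 1 to 3 and 5.19, 5.08, 5.25 and 5.05 in mutant replicates 1 to 4 (exact permutation p = 0.143). Their difference of 0.216 was 0.111 without control replicate 3. The 3 calls came to 0 without any of the controls, mutant replicate 2 or mutant replicate 4, to 5 higher without mutant replicate 1, and to 2 higher and 1 lower without mutant replicate 3. In the list of the ureteric bud and collecting duct, 2 of 20 tested members rose, 18 did not pass, and adjusted over the list alone 7 rose and 4 fell. Among those that rose was Calb1, a calcium-binding protein of the ureteric tree (43.1 ± 8.89 to 71.6 ± 5.43 FPKM). The ureteric list did not pass camera (median 0.01; adjusted p = 0.209). With a minimum of 5 FPKM it passed as higher (adjusted p = 0.049), 1 of 20 alternatives to do so, the others running up to 0.782. Both calls were lost without control replicate 1 or 2 or mutant replicate 2, 3 or 4. Without mutant replicate 1, 3 members were higher and 2 lower.

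**Figure D3:**
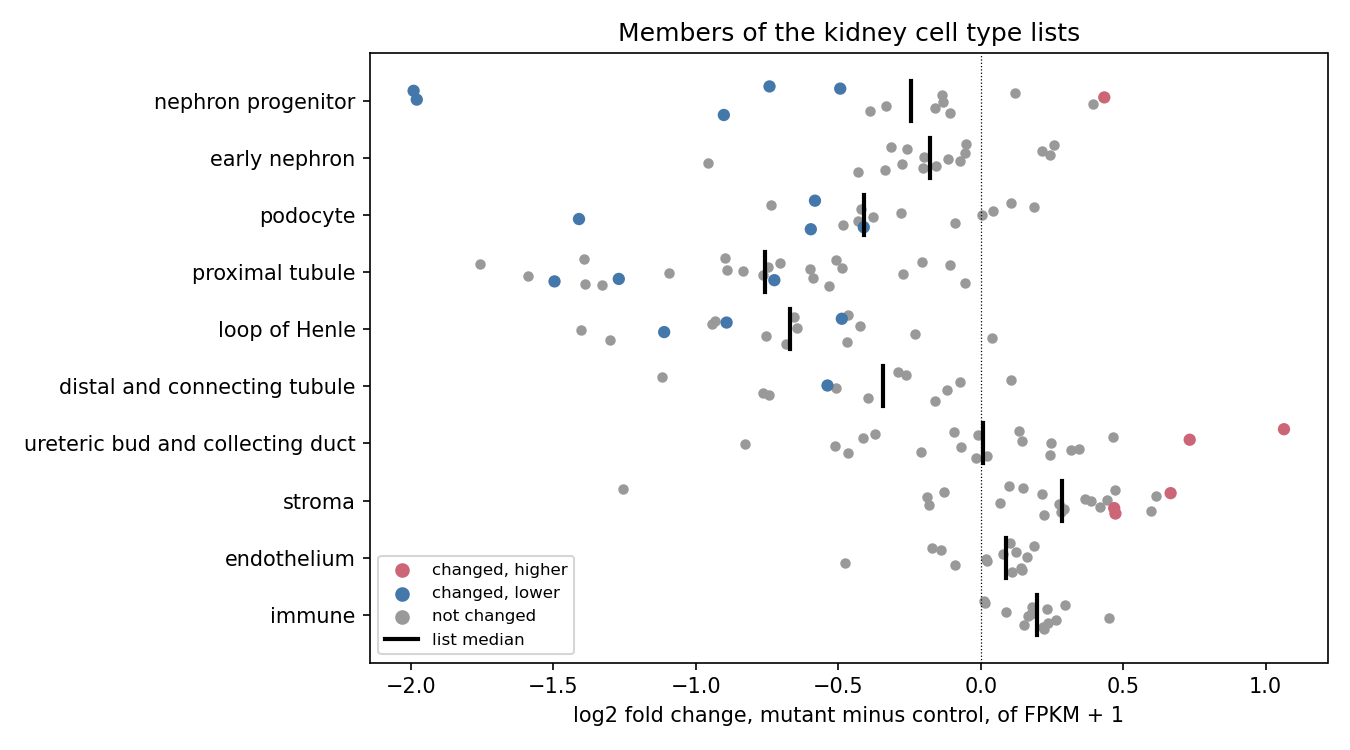
Log2 fold change, mutant minus control, of FPKM + 1 (horizontal axis) for each tested member of 10 cell type lists (rows); blue and red points fell and rose past limma's adjusted p threshold, grey points did not pass, and black bars are list medians. The medians run from -0.76 (proximal tubule) to 0.29 (stroma).

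Immune cell genes were higher as a list. They had a median of 0.20 with all 14 members above 0 (camera adjusted p = 6.28e-06; adjusted p = 0.129 with an estimated correlation), although 0 passed by limma, 6 had an unadjusted p under 0.05, 0 passed by limma-voom and 1 was higher in the deposited test, Pf4 (5.41 ± 0.47 and 7.79 ± 1.05 FPKM). Cell cycle genes had a median of 0.10 (camera adjusted p = 0.00514; adjusted p = 0.338 with an estimated correlation) and Wnt targets, among them Axin2 and Nkd1, a median of 0.18 (camera adjusted p = 0.0207; adjusted p = 0.173 with an estimated correlation). The cell cycle list did not pass with quantile normalization (camera adjusted p = 0.0832) or by fry (0.134). The Wnt list did not pass with array weights (camera adjusted p = 0.0663) or without control replicate 3 (0.0697) or mutant replicate 3 (0.0599). Erythroid, liver and mitochondrial lists were higher and the immediate early and heat shock list lower, with medians of 0.30, 0.61, 0.23 and -0.17, camera adjusted p of 0.0235, 0.0334, 0.0333 and 0.0235 and, with an estimated correlation, adjusted p of 0.49, 0.508, 0.516 and 0.412. The erythroid and liver lists did not pass without control replicate 1 (camera adjusted p = 0.477 and 0.168), control replicate 3 (0.0514 and 0.0861), mutant replicate 1 (0.161 and 0.443), mutant replicate 3 (0.0697 and 0.0932) or mutant replicate 4 (0.0522 and 0.405). The mitochondrial list did not pass without control replicate 3 (0.973), where its median was -0.0263. Nor did that list pass without mutant replicates 1, 2 and 4 (0.161, 0.123 and 0.0828), and the immediate early list did not without mutant replicate 2 (0.227). The lists of endothelium, skeletal muscle, neurons and glia, Hedgehog, BMP, FGF, hypoxia, the p53 response and the targeted locus did not pass camera, with adjusted p from 0.159 to 0.852. Skeletal muscle genes were high in control replicate 1 alone, where Actc1 was at 26.2 FPKM against 1.69 to 4.06 in the other libraries; the list passed without control replicate 2 (camera adjusted p = 0.0149) or 3 (0.0327). Of their members, Vegfa of the hypoxia list and Elavl4 of the neuron list fell (log2 fold change -0.28, SE 0.057, and -0.55, SE 0.088), and both lost the call in all omissions except that of mutant replicate 1. The adrenal and gonad lists had 1 tested member each. Mc2r, the receptor for adrenocorticotropic hormone, rose from 1.06 ± 0.13 to 1.87 ± 0.23 FPKM, a call lost in each of the 7 omissions, and Sox9 was at 8.54 ± 0.73 and 10.4 ± 0.49 FPKM (limma adjusted p = 0.133). The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were expressed in all 7 libraries.

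Of the 25 lists tested, 15 passed camera with its preset correlation, 8 lower and 7 higher. With an estimated correlation 0 passed and 7 had an unadjusted p under 0.05. Fry, also from limma, called 10, of which 9 were among the 15 in the same direction (6 lower and 3 higher). The exact permutation test of the list means called 0 after adjustment, with 5 at an unadjusted p under 0.05 and the smallest possible p at 0.0286. With that floor a list could pass after adjustment only if many of the 25 lay at it. In 11 lists, 10 of the 15 among them, all mutant means lay on the same side of all control means. The groups overlapped in the stromal, erythroid, liver, cell cycle and mitochondrial lists.

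The authors' deposited comparison, made with DESeq2, gave more calls. At an adjusted p under 0.05 it lists 886 genes, 282 higher and 604 lower in mutants, among them 205 of the 206 called by limma, in the same direction. Of the 886, 120 lay below the expression minimum used here. Its log2 fold changes, which carry no pseudocount, were 6.84 (SE 0.27) for Six3, -2.17 (SE 0.13) for Cited1, -1.27 (SE 0.17) for Irx3 and 0.03 (SE 0.29) for Irx5.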

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

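In 105 groups of 4 mutant values examined, 1 had a library far from the other 3 by Dixon's criterion, fewer than the 1 in 20 that chance gives. Mc2r was at 1.53 FPKM in mutant replicate 2 and at 1.97 to 2.02 FPKM in the other mutants.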

How the results depend on the processing

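The alternatives with limma-voom, the length trend, the globin covariate and the permutation of list means were chosen after seeing the data. The count of 206 changed genes (64 higher, 142 lower) came to 109 (65 lower) with a pseudocount of 0.1, 60 (31 and 29) with a minimum of 5 FPKM, 1302 (433 and 869) with array weights, 422 (129 and 293) with the length trend removed and 886 (282 and 604) in the deposited test; the smaller set of genes goes with the 5 FPKM minimum, and for the rest the cause was not tested. All 206 were among the 1302, 197 among the 422 and 205 among the 886. Leaving out a library gave 11 to 486 genes, 4 to 113 higher and 7 to 373 lower. With the replicate block 2 genes passed, 1 higher and 1 lower (Six3 and Cited1). Same-numbered libraries correlated at -0.16, 0.028 and 0.098, and differently numbered ones at -0.25 to 0.14. That gave no sign of pairing by number, but so few pairs cannot exclude it. The other settings gave 174 to 273 genes, with 40.8% higher under quantile normalization and 40.4% with a pseudocount of 0.1. Of the lists, 0 passed with an estimated correlation and 0 by exact permutation of their means, against 15. The permutation could hardly pass a list after adjustment over 25, since its smallest p is 0.0286, so its count of 0 does not count against the lists. Array weights left 10, without early nephron, erythroid (adjusted p = 0.627), liver (0.075), Wnt targets and immediate early (0.102). Quantile normalization left 11, without erythroid (0.0831), liver (0.061), cell cycle and mitochondrial (0.108). The 5 FPKM minimum gave 13, without erythroid (0.156) and immediate early (0.361) and with the ureteric list; the liver and skeletal muscle lists kept fewer than 3 members there and were not tested. Removing the length trend left 12, without erythroid (0.0546), liver (0.056) and mitochondrial (0.114). The liver list was lost with the replicate block (0.195) and the globin covariate (0.055), and the skeletal muscle list passed with no filter (0.021). A pseudocount of 0.1, median-of-ratios factors and limma-voom gave the same 15. The Irx3 difference of -1.16 was -1.02 to -1.24 without a library, with p at the smallest those designs can give, 0.0667 or 0.1; fewer samples are the cause.

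Differences near 0 changed sign. Irx5 was 0.0311 with quantile normalization, 0.029 in the deposited test, 0.0578 with array weights, 0.0163 with the globin covariate and -0.115 to 0.113 without a library (above 0 without control replicate 2 or 3 or mutant replicate 2 or 3: 0.000451, 0.0113, 0.113 and 0.0565). Kdm5d was 0.0341 with quantile normalization, 0.0721 with array weights, 0.0246 with the length trend removed and -0.0614 to 0.089 without a library. Fto was -0.0152 with array weights, -0.0062 with the globin covariate and -0.0112 to 0.0154 without a library. Uty was -0.0309 with the replicate block and -0.0711 to 0.159 without a library. Among lists, camera's direction turned for Hedgehog (median 0.0114 with the 5 FPKM minimum and -0.0196 to 0.148 without a library). It turned too for hypoxia (-0.0566 to 0.0739 without a library). For skeletal muscle (-1.44 to -0.0988 without a library) it turned without control replicate 1. That library alone was high in muscle genes, with a list mean of 4.17 against 1.75 to 1.96 in the others. Fry put the targeted locus higher (median -0.202). For that list, Hedgehog and hypoxia the cause was not tested. At 1 FPKM a gene of median length had 142 to 241 reads, and no fit at a lower depth was run.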

Other observations

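Of the tests in this part, the split counts, the length trend and the neighbours of Six3 were set before their results were seen, and the others after. Of 15 tested retinoid pathway genes, a list drawn up after the rises of Aldh1a2 and Aldh1a3 in it had been seen, 5 rose (Aldh1a3, Dhrs3, Aldh1a2, Tgm2 and Rdh10) and 10 did not pass. A fold change above 0 was seen in 14, with a median of 0.35. Aldh1a2 and Rarb are also members of the stromal list, whose median was 0.29. The retinoid list mean went from 4.19 ± 0.0063 to 4.55 ± 0.085 (n = 3 and 4; exact permutation p = 0.0286, or 0.0571 adjusted over the 2 lists made this way). The retinoic acid-degrading Cyp26b1 was at 4.43 FPKM in controls and 7.02 in mutants and did not pass. A joint rise of the pathway may be worth a test in other kidneys, since these libraries do not decide it.

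A list of differentiated urothelium and distal ureteric epithelium, drawn up after Sprr2g and other large rises had been seen, had 4 of 15 members higher (Cldn4, Krt80, Klf5 and Elf3) and 11 that did not pass, with a median of 0.13. Its mean was 2.25 ± 0.12 in controls and 2.45 ± 0.13 in mutants (n = 3 and 4; exact permutation p = 0.114, and 0.114 adjusted), so no joint rise was shown. The 4 tested uroplakin genes, Upk1a, Upk1b, Upk3a and Upk3b, were at 1.57, 1.80, 6.66 and 0.710 FPKM in controls and at 1.43, 1.54, 4.46 and 0.866 in mutants, and did not pass.

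Chance in the grouping of the libraries is an unlikely source of the count of changed genes. Of the 35 splits 1, the real one, gave 206, and the highest of the others gave 13. A share of 1 in 35 (0.0286) is the smallest that this design can give. For the lists the split counts do not exclude chance in the grouping. The real split alone of the 35 gave 15, but the highest other gave 14. That other split set mutant replicate 4 with the controls against the other mutants. These counts of lists use camera's preset correlation, and with an estimated correlation 0 lists passed in the real split.

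The fall of nephron segment genes was weighed against embryo age, a uniform loss of nephron cells and a length trend. Age, read from the beta-globin ratio, moves with the proximal list within groups, yet with the ratio as a covariate the group difference stayed at -0.708 (SE 0.094), and at -0.688 (SE 0.11) without mutant replicate 3. A uniformly lower share of nephron cells would lower early and late genes alike if both lists were equally confined to nephron cells. The proximal mean fell further than the early nephron mean by -0.674 (SE 0.23), or -0.505 (SE 0.14) without mutant replicate 3. How far the early genes are confined to nephron cells was not tested, and 3 of the 16 had a fold change above 0. The gap therefore does not decide whether nephron cells were uniformly fewer. Mutant replicate 1 has a trend on transcript length (median deviation 0.179 in the shortest 10% of genes and -0.256 in the longest 10%), and with such trends removed the proximal difference was -0.839 (SE 0.24). A slower or blocked maturation of the nephron may remain as a hypothesis, beside a loss of nephron cells. An effect of Cre or of Six3 cannot be told apart from that of the deletion. Every mutant carries Six2-Cre and has Six3 RNA, and the control labels name no Cre. A difference in age that globin does not record was not tested.

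Six3 RNA was in 4 of 4 mutants and near 0 in the controls. An exchange of a mutant with a control is excluded by Irx3, since 0 mutant libraries lay above the lowest control in it (12.7 FPKM). Of the 10 tested genes nearest to Six3, 0 rose by limma (1 at an unadjusted p under 0.05, 0 by limma-voom, 1 in the deposited test) and 1 fell, the proximal tubule gene Slc3a1 (2 lower at an unadjusted p under 0.05, 0 by limma-voom, 1 in the deposited test). This argues against a rise of the whole neighbourhood. A candidate explanation is Six3 copied with the Six2-Cre transgene, which would mark Cre and not the loss of Irx3 and Irx5. It cannot be told apart from an effect of the deletion, since all 4 libraries with Six3 carry both and no library has Cre with intact Irx3 and Irx5.

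Cited1 and Uncx had the 2 largest falls of the progenitor list (-1.99 and -1.98). A uniform loss of progenitors as the whole cause would lower all members about as much. The median of the whole list was -0.246 (SD 0.747 over the 14 members). Because Cited1 and Uncx were picked as its largest falls, some gap to that median was fixed by the choice. The gap therefore does not decide whether progenitors were lost, and a loss stays open. Sequence near the floxed locus is unlikely as the source, because 0 of the 20 tested genes nearest to Irx3 changed by limma (1 at an unadjusted p under 0.05, 0 by limma-voom, 1 in the deposited test) and these 2 genes lie on other chromosomes. Regulation by Irx3 or Irx5, by ectopic Six3, or an effect of Cre itself may each be involved, and the design does not separate them.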
